A study of Mus musculus with 6 samples.

How the data were processed

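Single nuclei from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, were profiled by droplet RNA sequencing on the 10x Genomics platform with its 5′ kit, per the labels' protocols. The labels describe 6 libraries, 3 named Control and 3 named S.aureus IMQ, with 10000 nuclei loaded on each lane. The series title places the study in psoriasis. The submitters' processing notes name Cell Ranger 7.1.0, R 4.4.2, Seurat 4.4.0 and the mouse build mm10. They do not say which tool made which file, and the annotation release is not given in the sources used here.

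A list of droplet barcodes and a list of genes were analysed. The matrix of UMI counts was not analysed here, so no gene has an expression value, no nucleus has a depth or a cell type, and no gene was tested between the groups. The designed tests of pooled nuclei, neurons, cell classes, cell shares and gene lists were therefore not run. Each line of the barcode list is a sequence of 16 bases followed by a library suffix from 1 to 6, and the list is named as a filtered one, which in Cell Ranger output means barcodes that passed cell calling. Doublets, droplets that hold more than 1 nucleus, were not assessed and no barcode was removed as one, since a doublet caller needs the counts, and whether any were removed before deposit is not given in the sources used here. The gene list gives an Ensembl identifier, a symbol and a feature type per line.

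The suffixes were not assigned to samples. The sample titles number both groups from 1 to 3 and the library names count lanes from 1 to 6, but nothing read here states that suffix and lane number are the same. The suffixes therefore enter no comparison between Control and S.aureus IMQ, and their values are given one by one with the range and median. Nothing in the labels says how many animals contributed to a library.

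Barcodes were counted per suffix in Python 3.11.15. Each library's share of all barcodes has a 95% Wilson binomial interval (scipy 1.17.1), which covers counting error only. For each of the 15 pairs of libraries, the number of identical barcode sequences was compared with that of random draws from the kit's list of 737280 barcodes, a size taken from general knowledge of the kit, with an exact two-sided hypergeometric test and Benjamini-Hochberg adjustment over the 15 pairs. The sum over pairs was compared with 10000 simulated draws (numpy 2.4.6), in which pairs were drawn independently. The difference between shared and expected barcodes was tested on simulated pairs of libraries with known numbers of carried-over barcodes. The p-values, the sum over pairs and the bounds were not tested in this way.

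Gene identifiers were matched, without version, to GENCODE release M21 on GRCm38, the assembly that mm10 names. This release was chosen as the annotation at hand. Of the 32285 identifiers, 32235 matched and 50 did not, and 31502 had the same symbol in both. Coordinates are 1-based. Before the data were examined, 13 gene lists and 18 sets of cell type markers were fixed, holding 331 different symbols, and only these were looked up. Among them, Fam19a4 and Tafa4 name the same gene. A listed gene was said to overlap another where both lie on the same strand, first over the whole gene and then over annotated exons. The alternatives counted only barcodes found in 1 library, dropped barcodes with a neighbour 1 base away, left out each library in turn, estimated the barcode list's size from the data, allowed 1 base of difference between libraries, and kept only genes with a unique symbol.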

Results

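Nuclei of mouse dorsal root ganglion were collected in 6 libraries, 3 from Control and 3 from S.aureus IMQ mice, to examine skin-innervating sensory neurons in a psoriasis setting. The filtered barcode list held 48107 barcodes over 6 library suffixes. Transcript counts were not analysed here, so the values below describe how many barcodes each library contributed and which genes the reference could count. They include no expression level and no difference between Control and S.aureus IMQ.

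The number of barcodes per library ranged from 4630 to 10947, with a median of 8318, and the largest library had 2.36 times as many as the smallest. Suffix 1 had 5565 barcodes, which was 11.57% of all barcodes (95% Wilson interval 11.29 to 11.86%). Suffix 2 had 10329 barcodes, or 21.47% (21.11 to 21.84%). Suffix 3 had 10947 barcodes, or 22.76% (22.38 to 23.13%). Suffix 4 had 4630 barcodes, or 9.62% (9.36 to 9.89%). Suffix 5 had 9151 barcodes, or 19.02% (18.67 to 19.38%), and suffix 6 had 7485 barcodes, or 15.56% (15.24 to 15.89%). The intervals cover counting error only. The spread between replicates of a group could not be given, because the suffixes were not matched to samples. With 3 libraries per group, an exact two-sided permutation test of barcode number would in any case be limited to 0.10 at the lowest.

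**Figure D1:**
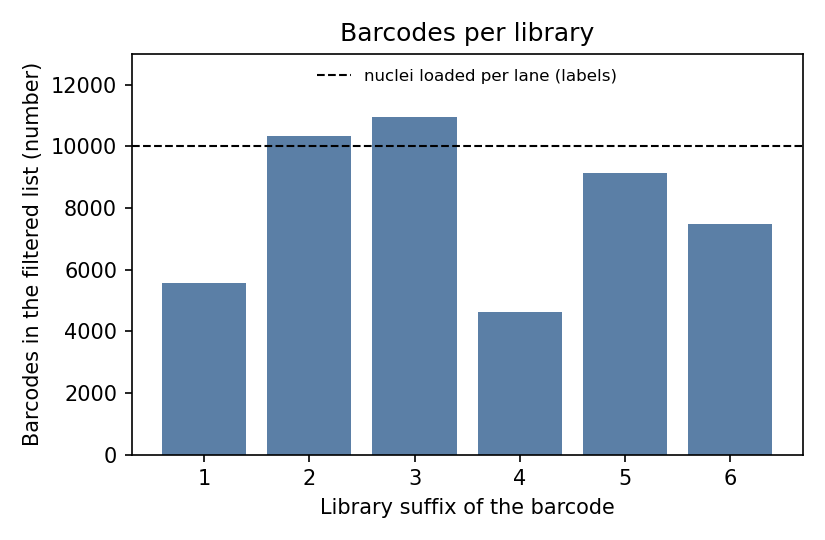
Number of barcodes in the filtered list (vertical axis) for each of the 6 library suffixes (horizontal axis), 1 bar per library and without error bars, with a dashed line at the 10000 nuclei loaded per lane. Suffixes 2 and 3 lie above the line, at 10329 and 10947 barcodes, and suffix 4 is lowest, at 4630.

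Relative to the 10000 nuclei loaded per lane, the barcodes of suffix 4 came to 46.3% and those of suffix 1 to 55.6%. Suffixes 6 and 5 reached 74.8% and 91.5%. Suffixes 2 and 3 held more barcodes than the stated number of loaded nuclei, at 103.3% and 109.5%. Over all lanes, the 48107 barcodes were 80.2% of 60000 loaded nuclei.

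The 48107 barcodes comprised 46779 different sequences. Of these, 45469 occurred in 1 library, 1292 in 2 libraries, 18 in 3 libraries and 0 in more than 3. Summed over the 15 pairs of libraries, 1346 barcodes were shared, against 1285.5 expected for random draws from the kit's barcode list, a ratio of 1.05. The middle 95% of simulated draws ran from 1218 to 1356, and the two-sided p of the sum from these simulations was 0.091. Among single pairs the ratio ranged from 0.88 to 1.17. By the exact hypergeometric test, 0 of the 15 pairs had an unadjusted p under 0.05, and 0 had an adjusted one. The smallest unadjusted p was 0.077, with an adjusted value of 0.906, for suffixes 3 and 5, which shared 157 barcodes where 135.9 were expected. Sharing beyond that of independent draws, with each barcode of the kit's list equally likely, was thus not detected with all 6 libraries. That equal likelihood was not tested, so a ratio above 1 need not mean that libraries depend on each other. Without suffix 1 the ratio of 1.07 had a simulated two-sided p of 0.021. That was the smallest p when each library was left out in turn, and the others ran from 0.055 to 0.502. These leave-outs were chosen after seeing the data, and their p-values were not adjusted for the number of leave-outs. The barcode sequence alone, without its suffix, does not name 1 nucleus in this list.

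The gene list defined what could be counted in these nuclei. It held 32285 features of 1 type, gene expression. By the GENCODE annotation, 21702 were protein-coding genes, 9830 belonged to long non-coding RNA classes and 697 were immunoglobulin or T cell receptor segments. All 13 mitochondrial features were protein-coding genes. The list held 1 of the annotated processed pseudogenes, with 9940 outside it, and 0 miRNA genes, with 2207 outside it.

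By the same annotation, 21702 protein-coding genes were listed and 326 were not, so nearly all members of most gene sets would be found. The lookups that follow therefore describe the reference and not these nuclei. The markers fixed for sensory neuron types were all listed, 1 of them under a newer symbol. All 6 markers of Mrgprd-expressing non-peptidergic nociceptors, all 4 of Mrgpra3 itch neurons, all 7 of Sst and Nppb itch neurons, all 8 of peptidergic nociceptors and all 4 of cold-sensing neurons were found by symbol. Mrgprd, a receptor gene of non-peptidergic nociceptors, lies on chromosome 7 at 145314835 to 145324086 (GRCm38, plus strand). Mrgpra3, which encodes a chloroquine-responsive itch receptor, lies on the same chromosome at 47588950 to 47601372 on the minus strand. Il31ra and Osmr, whose products together form the interleukin-31 receptor, lie on chromosome 13 at 112519898 to 112594360 and on chromosome 15 at 6813577 to 6874969, both on the minus strand. Calca, which encodes the neuropeptide CGRP, lies on chromosome 7 at 114631478 to 114636357. The C-fibre low-threshold mechanoreceptor marker Fam19a4 was the 1 marker not found under the symbol searched. Its identifier, ENSMUSG00000046500, was listed under the newer symbol Tafa4, on chromosome 6 at 96831203 to 97060413. Tafa4 was itself in that marker set and was found, so the set held this gene under both names. Together 17 of the 18 marker sets, which also covered glia, fibroblasts, vessels and immune cells, were found completely by symbol.

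Of the 13 fixed gene lists, 12 were found completely, which again describes the reference only. These included all 19 genes for nerve injury and regeneration, all 17 neuropeptides, all 22 nociceptor ion channels, all 30 cytokine receptors and signalling genes and all 19 genes for microbial sensing. Among the last were Tlr7, which encodes an endosomal sensor of single-stranded RNA and lies on chromosome X at 167304929 to 167330558, and Tlr2, which encodes a sensor of bacterial lipoproteins and lies on chromosome 3 at 83836272 to 83841767. The interferon response list had 21 of its 23 genes. The 2 not found were the antiviral genes Mx1, on chromosome 16 at 97447035 to 97462907, and Mx2, on chromosome 16 at 97535308 to 97560900, and neither was listed by its identifier. Interferon-induced genes such as Isg15, Ifit1 and Irf7 were listed.

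Of the listed genes that were looked up, 23 overlapped another listed gene on the same strand, and for 8 the overlap included exons of both. The 8 were Fpr2 with Fpr3, Irf9 with Rnf31, L1cam with Arhgap4, Nmb with Sec11a, Rtp4 with Gm45338, mt-Atp6 with mt-Atp8 and mt-Co3, mt-Co3 with mt-Atp6, and mt-Nd4 with mt-Nd4l. Reads from such shared stretches cannot be given to 1 gene by position alone. Among the 15 others, the overlap lay outside shared exons, as for the neuronal gene Rbfox3 with Gm11749 and the Toll-like receptor adaptor gene Myd88 with Slc22a14.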

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

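The alternatives that leave out libraries from the shared-barcode ratio were chosen after seeing the data. The median number of barcodes per library, 8318, became 7854 when only barcodes found in 1 library were counted and 7485 to 9151 when each library was left out in turn. The ratio of shared to expected barcodes, 1.05, ranged from 1.02 to 1.07 when each library was left out. Without suffix 1 it was 1.07 with a simulated two-sided p of 0.021, not adjusted for the number of leave-outs. The unadjusted p was under 0.05 only there, not with all libraries, nor without any other library (p from 0.055 to 0.502). Estimating the barcode list's size from the same pairs gave 704155 sequences and fixes the ratio at 1.00, so it tests nothing. Allowing 1 base of difference, or dropping barcodes with a neighbour 1 base away, could move nothing, because 0 of the sequences had such a neighbour. These alternatives therefore test nothing either. Keeping genes with a unique symbol left 32207 of 32285, and restricting the feature type removed none. Other settings of the expression, cell-share and gene-list tests were not run, since counts were not analysed here. No paired analysis was possible because the library suffixes were not matched to samples.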

Other observations

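The tests in this part were chosen after the barcode numbers were seen. Suffixes 2 and 3 held 329 and 947 more barcodes than the 10000 nuclei stated to be loaded per lane, although fewer barcodes than loaded nuclei are usually recovered from a droplet run. One technical explanation is that barcodes were carried over from other libraries. This would add shared barcodes where these also passed cell calling in the other library. Suffix 2 shared 537 barcodes with the other 5 libraries where 529.3 were expected, an excess of 7.7 with an upper bound of 51, and suffix 3 shared 594 where 551.7 were expected, an excess of 42.3 with an upper bound of 87. Both bounds lie below the surplus, which argues against carry-over of barcodes listed for the other 5 libraries as its whole source. Carry-over from libraries outside this list could not be seen by such a count and was not tested. The same holds for barcodes that did not pass cell calling in the library they came from. A loaded number that is nominal, and droplets with free RNA counted as nuclei, stay open, since the first needs the loading record and the second the UMI counts, and no biological explanation was tested. Doublets were not assessed, so a barcode in these numbers can stand for more than 1 nucleus.

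Names matter for any search of this gene list by symbol. There were 38 symbols that belonged to more than 1 identifier, covering 78 features. They included the chemokine genes Ccl19, Ccl21a, Ccl21b and Ccl21c with 2 identifiers each, Ccl27a with 3, the interleukin-11 receptor gene Il11ra2 with 3, and the stress-response gene Ddit3 with 2. These were noticed after the list was seen, and none is a member of the fixed lists. A value for such a symbol would cover only part of what the list assigns to that name if only 1 identifier were read. The interferon gene Mx2, which was not found, is annotated as a polymorphic pseudogene in the release used here, and the list held 0 genes of that class with 82 outside it. Mx1 is annotated as protein-coding in that release, in which 326 protein-coding genes were outside the list in all. The release behind the list is not known, so whether Mx1 had another class there cannot be told.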
